A study of Chlamydomonas reinhardtii with 12 samples.

How the data were processed

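The data are 12 two-colour cDNA microarrays of Chlamydomonas reinhardtii, each with total RNA of wild type CC-125 in 1 channel and of npq1 lor1 in the other. There were 3 time points (low light, 1 h and 6 h of high light), 2 biological samples per time point and 2 slides with exchanged dyes per biological sample, per the labels. The values used are log2 ratios that the authors normalized with SNOMAD before they were deposited, per the labels; SNOMAD's settings, the background correction and the filter on weak spots are not given in the sources used here. Per the labels, the ratio is Cy3 over Cy5 on the 6 slides with wild type in channel 1 and Cy5 over Cy3 on the 6 with the mutant in channel 1. The dye of each channel is not stated. The ratios therefore run the same way on all slides if channel 1 always held the same dye, and no sign was turned. Scanner intensities were not analysed here.

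The scale (log2) is known from the labels, the centring is not stated, and the direction stays open as described in the results. Medians of the deposited values without zeros lay between 0.04 and 0.17 on the slides with wild type in channel 1 and between -0.17 and -0.02 on those with the mutant. No further normalization was applied in the main test.

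The 11520 spots were read as 4 copies of 2880 elements, 2880 spot numbers apart. This layout was inferred from the table of probe names, in which all 106 clone accessions stand on 4 spots at that distance, and from the correlation between copies, which had a median r of 0.61 over slides (0.24 to 0.92). Values of exactly 0 were treated as missing, since 623 spots were 0 on all slides and a ratio rarely equals 1 exactly; this reading was chosen after the values were seen. An element's value on a slide was the mean of at least 2 spots. The exchanged slides of a biological sample come from the same RNA extracts, so their mean was taken as 1 replicate and both slides had to have a value. An element was tested where both biological samples of the time points involved had values.

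Strain differences were tested with limma 3.58.1 in R 4.3.3 on 6 values per element, with a mean for each of the 3 time points and 1 moderated spread per element over all time points (lmFit and eBayes, prior degrees of freedom 5.66, prior SD 0.108). Each mean was tested against 0 and each pair of means against each other, two-sided, with Benjamini-Hochberg adjustment over the elements tested and a threshold of 0.05. The labels call the samples biological replicates. Elements at least 2-fold from equality in both biological samples were counted without a test, beside the number expected if the 2 samples were unrelated. With 2 biological samples per time point, other splits of the samples were not counted.

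The procedure was tested on simulated data with 200 elements changed in each run. Elements were simulated as independent, with dye effects and missing values taken from the data. The dye effect of an element was equal and opposite on exchanged slides, so it cancelled in their mean and its harm was not tested. Slide noise was the same share of the element's spread on every slide. Each element's spread was drawn from limma's fitted prior and was the same at all 3 time points. At a log2 size of 0.5 it recovered 91% of them among 2396 elements in low light, 96% among 2272 at 1 h and 93% among 2139 at 6 h. At a size of 1 it recovered 100% at each time point. False calls numbered 8 of 190, 15 of 207 and 4 of 190 at the size of 0.5, and 3 of 203, 6 of 206 and 11 of 211 at the size of 1. With no element changed it made 0 calls. These rates follow from the test's own assumptions, which the data do not fully meet. Over the elements tested at both times, the median size of the difference between biological samples was 0.073 in low light and 0.117 at 6 h. Neighbouring spots correlated with r up to 0.65. The median SD between copies ran from 0.046 to 0.351 over slides.

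Locus tags came from the platform's annotation: 420 spots (105 elements, 100 loci) had 1 locus, 4 spots had several and were not named, and 11096 spots had none. All 100 loci were found in the reference gene table of assembly Chlamydomonas_reinhardtii_v5.5, which gives no symbols other than locus tags. Coordinates are not printed, because no build is named for the array. For 4 loci with more than 1 element, elements were kept apart. The 21 gene lists fixed beforehand (the mutated genes, light-harvesting and photosystem proteins, carotenoid synthesis, antioxidant enzymes, chaperones and others) could not be matched to locus tags and had 0 members, so the camera test of lists was not run and the mutated genes were not analysed here.

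Elements were named by a rule fixed before the data were examined: at each time point up to 10 per direction, largest in size among those past the threshold with the same sign on every slide with a value (at least 3 slides), and at most 2 per direction where no locus is given. For changes between time points up to 5 per direction were named, and the few counted by the 2-fold rule were named as well.

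The alternatives fixed beforehand were centring or scaling each slide, all 12 slides with the biological sample as a random block with or without a dye term, slides of 1 orientation, elements with values on all slides, spread from the time point's own samples, robust eBayes, medians of spots, the replicate number as a block and leaving out each biological sample. Added after the data were seen were other spot minimums, zeros kept as values, subtraction of a running median of 36 neighbouring spots on each side, array weights, a crossed block, and the omission of 3 slides whose copies correlated below 0.4. The omission of slides was run in the fit with the biological sample as a random block and a dye term. Figures were drawn with matplotlib 3.10.9.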

Results

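Cultures of the green alga Chlamydomonas reinhardtii were compared between the wild-type strain CC-125 and the double mutant npq1 lor1 in low light and after 1 h and 6 h of high light. The npq1 mutation blocks the conversion of violaxanthin to zeaxanthin and the lor1 mutation blocks the formation of lutein, so that the double mutant lacks xanthophylls that protect the chloroplast against excess light. RNA of both strains was hybridised together on 2-colour cDNA microarrays. Each of the 3 time points had 2 biological samples, and each biological sample was measured on 2 slides with the dyes exchanged, which gave 12 slides. The question addressed was which transcripts differed between the strains before the shift, and whether that difference moved during the shift.

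The array held 11520 spots, which stood for 2880 elements in 4 copies. Between 848 and 5000 spots per slide (7.36% to 43.4%) had a deposited value of exactly 0 and were treated as not measured. Values for at least 2 copies were left for 2202 to 2699 elements per slide. A locus tag could be attached to 105 elements, and the other elements are given by the number of their first spot. The number of slides limits the precision. With 2 biological samples per time point, the median standard error of a mean log2 ratio was 0.0744 in low light, 0.0745 at 1 h and 0.0748 at 6 h. These are alike because the fit uses 1 spread per element for all time points. The median size of the difference between biological samples was 0.073 in low light and 0.117 at 6 h, over elements tested at both. It was 0.129 over those tested at 1 h.

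All slides were deposited as ratios that run the same way, provided channel 1 carried the same dye on every slide. The labels do not state that dye. The ratio is likely wild type over npq1 lor1, because the titles name the strains in this order and because this direction follows if channel 1 was Cy3. Ratios are therefore reported with their deposited sign, and a negative ratio would mean more transcript in npq1 lor1 under that reading. The reading as a strain difference rests on the labels: if the slides with exchanged channels had not been turned as described, the means over them would hold dye effects in its place.

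Single slides resembled each other by the strain in channel 1 more than by time point. Over the 30 pairs of slides with the same strain in channel 1, Pearson's r across elements lay between 0.31 and 0.83. Over the 36 pairs with exchanged channels it lay between -0.57 and 0.13, and 33 of these pairs were below 0. The mean of the exchanged slides of a biological sample correlated across elements with r = 0.62 between the 2 biological samples in low light, 0.38 at 1 h and 0.42 at 6 h. Elements are not independent replicates. In all 20 instances, from 13 elements, in which an element was at least 2-fold from equality on both exchanged slides of a biological sample, the ratio had the same sign on both slides.

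**Figure D1:**
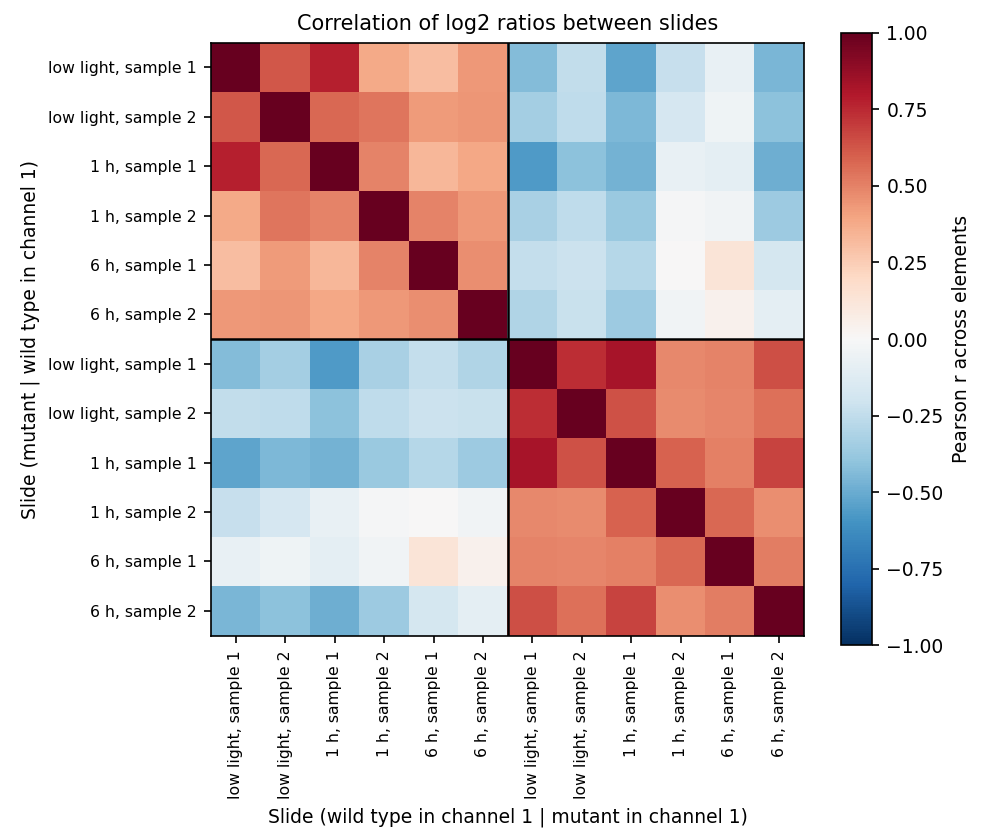
Pearson correlation across elements of the log2 ratios of every pair of the 12 slides, ordered by the strain in channel 1 and then by time point and biological sample (colour scale from -1 to 1). Slides with the same strain in channel 1 correlate between 0.31 and 0.83, and slides with exchanged channels between -0.57 and 0.13.

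In low light, 8 elements differed between the strains, 7 with a negative and 1 with a positive ratio. The locus-tagged element among them was CHLRE_17g720250v5, with a mean log2 ratio of -0.48 ± 0.11 (SD, n = 2, limma adjusted p = 0.0342), a 1.40-fold difference. The most negative ratio among the 8 was that of element 1198, at -1.10 ± 0.24 (SD, n = 2, adjusted p = 0.0111), and element 1360 had -0.84 ± 0.17 (SD, n = 2, adjusted p = 0.0256). Element 293, with -0.89 (adjusted p = 0.0111), also passed but had both signs among its slides and so fell outside the rule for naming. Element 2850 had the positive ratio, 0.65 ± 0.14 (SD, n = 2, adjusted p = 0.0291). In all, 2396 elements were tested.

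The sizes of the 8 ratios ran from 0.44 to 1.10 on the log2 scale, and 6 of the 8 had the same sign on every slide with a value. Adjusted over the 94 tested locus-tagged elements alone, limma's p passed for 4 of them. At an unadjusted p under 0.05 there were 191 elements, where 119.8 would be expected by chance. The count rose to 114 when the low light samples alone set the spread, and fell to 1 without either biological sample of 1 h. Over the alternatives with both dye orientations, calls were lost in 5 of 21 for CHLRE_17g720250v5 (adjusted p from 0.00123 to 0.642, the latter without biological sample 2 of low light), 5 of 21 for element 2850, 4 of 20 for element 1360 and 2 of 21 for element 1198.

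After 1 h of high light, 16 elements differed between the strains, 11 with a negative and 5 with a positive ratio, and none of them carried a locus tag. Among these 16, element 911 stood farthest from equality, with a mean log2 ratio of -1.50 ± 0.15 (SD, n = 2, limma adjusted p = 1.23e-04), a 2.82-fold difference. Element 1445 followed with -1.07 ± 0.20 (SD, n = 2, adjusted p = 0.0185). The most positive ratios among the 16 were those of element 2039, at 0.65 ± 0.10 (SD, n = 2, adjusted p = 0.0185), and element 1094, at 0.57 ± 0.19 (SD, n = 2, adjusted p = 0.0312).

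Of 2272 tested elements, 267 had an unadjusted p under 0.05, against 113.6 expected by chance, and 13 of the 16 had the same sign on every slide with a value. Of the 93 tested locus-tagged elements, 44 had a positive and 49 a negative ratio, with a median of -0.01, and 0 passed with limma's p adjusted over the locus-tagged elements alone. The count was 81 when the 1 h samples alone set the spread, and 4 and 1 without biological sample 1 or 2 of that time point. Element 911 passed in each of 21 alternatives that used both dye orientations, with adjusted p up to 0.0368, while calls were lost in 5 of 21 for element 1094, 3 of 20 for element 1445 and 2 of 21 for element 2039.

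After 6 h of high light, 43 elements differed between the strains, 36 with a negative and 7 with a positive ratio. All 8 locus-tagged elements among them had negative ratios. The 2 most distant were CHLRE_08g365900v5, with a mean log2 ratio of -1.03 ± 0.18 (SD, n = 2, limma adjusted p = 0.00358, a 2.04-fold difference), and CHLRE_16g673650v5, with -0.94 ± 0.01 (SD, n = 2, adjusted p = 0.00101, a 1.92-fold difference). CHLRE_08g372450v5 had a ratio of -0.63 ± 0.09 (SD, n = 2) and CHLRE_03g182551v5 one of -0.61 ± 0.33 (SD, n = 2). Among the elements past the test without a locus tag, element 1198 at -1.25 ± 0.31 (SD, n = 2) and element 2847 at -0.97 ± 0.27 (SD, n = 2) were the most negative, and elements 654 at 0.55 ± 0.11 (SD, n = 2) and 819 at 0.53 ± 0.01 (SD, n = 2) the most positive.

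The other 4 loci had smaller ratios. CHLRE_03g158000v5 had a mean log2 ratio of -0.53 and CHLRE_10g420350v5 one of -0.50. CHLRE_05g238332v5 had -0.46, and CHLRE_17g720250v5 had -0.41 at 6 h after -0.48 in low light. The adjusted p of these 4 loci lay between 0.00899 and 0.0219. At 1 h the ratio of CHLRE_17g720250v5 was -0.09, and its changes from low light (adjusted p = 0.450) and to 6 h (adjusted p = 0.359) did not pass the test. When the p-values were adjusted over the 79 tested locus-tagged elements alone, 11 of them passed.

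**Figure D2:**
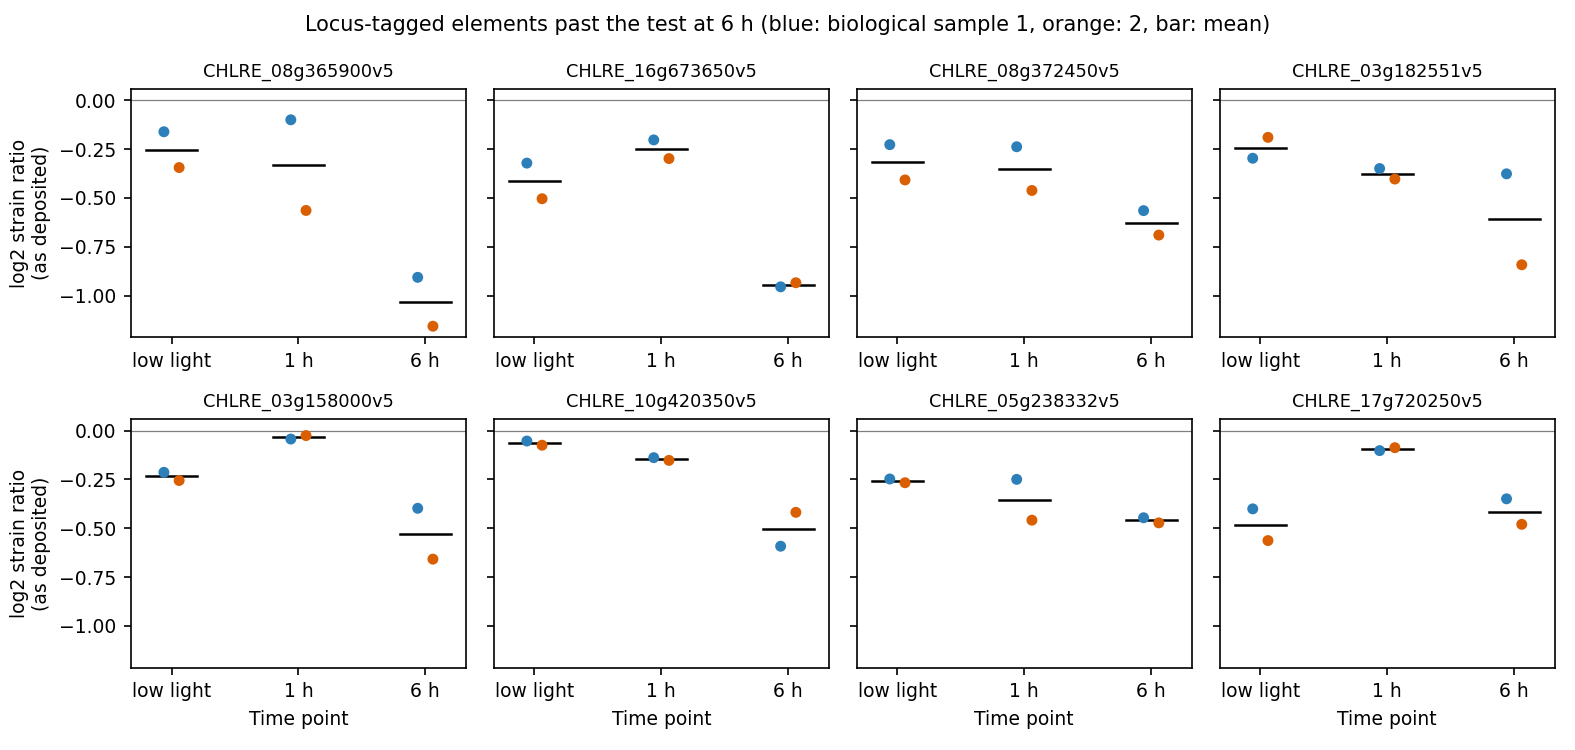
Mean log2 strain ratio of the 2 exchanged slides (vertical axis, deposited sign) at the 3 time points (horizontal axis) for the 8 locus-tagged elements that passed the test at 6 h. Each point is 1 biological sample and each bar the mean of 2, and the lowest mean at 6 h is -1.03, for CHLRE_08g365900v5.

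Of 2139 tested elements, 461 had an unadjusted p under 0.05 at 6 h, against 106.95 expected by chance, and 38 of the 43 had the same sign on every slide with a value. The number at an unadjusted p under 0.05 was 265 with the running median of neighbouring spots subtracted. With each time point's own samples setting the spread, it was 368 at 6 h and 423 in low light. CHLRE_08g365900v5, CHLRE_16g673650v5 and elements 1198, 2847 and 819 passed in each of 21 alternatives that used both dye orientations, while CHLRE_17g720250v5 lost its call in 5 of 21 and CHLRE_03g182551v5 in 4 of 20. Slides of a single orientation, in which any dye effect would not cancel, gave 438 elements, 328 of them positive, with wild type in channel 1, and 21, 20 of them negative, with the mutant there. Element 819 lost its call on slides with the mutant in channel 1, at 0.41 (limma adjusted p = 0.175). The higher count at 6 h than in low light (43 against 8) did not hold when each time point's own samples set the spread, where the counts were 64 and 114, and it was not tested as a difference.

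**Figure D3:**
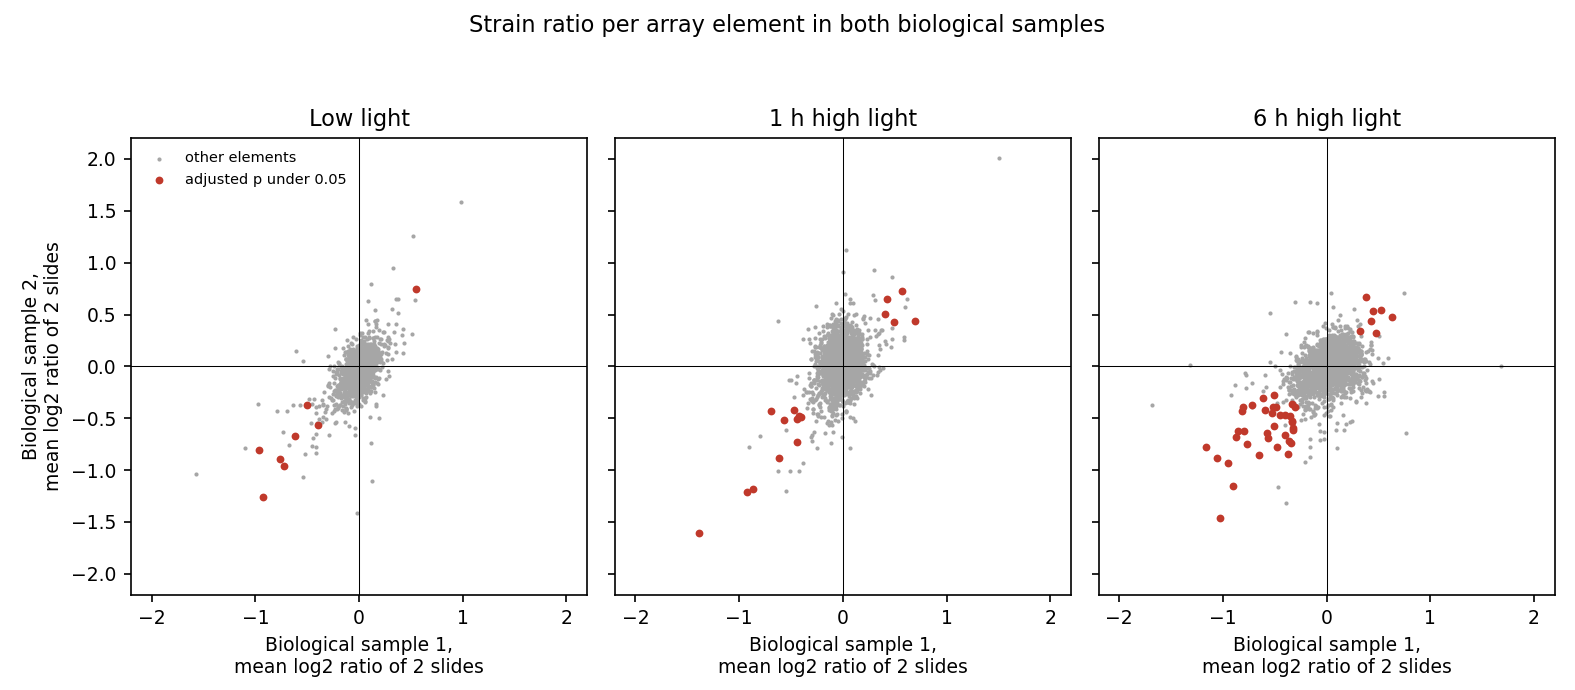
Mean log2 strain ratio of each element in biological sample 1 (horizontal axis) and biological sample 2 (vertical axis) at each time point, with the elements past limma's adjusted p of 0.05 in red. There are 8 red elements in low light, 16 at 1 h and 43 at 6 h, most of them with negative ratios in both samples.

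The strain ratio moved during the shift for 5 elements, 1 of them locus-tagged. The ratio of element 911 was -0.27 ± 0.20 (SD, n = 2) in low light, -1.50 at 1 h and -0.23 ± 0.03 (SD, n = 2) at 6 h. It fell by 1.23 on the log2 scale from low light to 1 h (SE 0.12, limma adjusted p = 0.0105) and rose by 1.27 from 1 h to 6 h (SE 0.12, adjusted p = 0.00722). CHLRE_16g673650v5 fell by 0.69 from 1 h to 6 h (SE 0.10, adjusted p = 0.0412), from -0.25 to -0.94. At 1 h its slides had 0.16 and 0.15 with wild type in channel 1, and -0.56 and -0.75 with the mutant there. Its mean at 1 h thus averages opposite signs, and the SE leaves out the spread between exchanged slides. Element 1734 fell by 0.63 and element 630 rose by 0.67 over the same interval (SE 0.09 for each, adjusted p = 0.0412 for both). Exchanged slides also had opposite signs for element 1734 at 1 h and for element 630 at 6 h, in both biological samples.

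From low light to 6 h, 1 of 2032 tested elements passed, element 293, whose ratio rose by 1.13 (SE 0.13, adjusted p = 0.0403) from -0.89 to 0.24. From low light to 1 h 1 of 2195 and from 1 h to 6 h 4 of 1925 elements passed. The numbers at an unadjusted p under 0.05 were 113, 235 and 175 for the changes to 1 h, to 6 h and between them, against 109.75, 101.6 and 96.25 expected by chance. With the running median of neighbouring spots subtracted they were 126, 137 and 177. The excess for the change to 6 h thus depended largely on regional trends. The change of element 293 lost the call in 10 of 20 alternatives with both orientations, with sizes down to 0.63, and its low light ratio in biological sample 2 averaged 0.65 and -2.26 on the exchanged slides, the latter from 2 spots. The changes from 1 h to 6 h lost their calls in 12 of 21 alternatives for CHLRE_16g673650v5, 11 of 21 for element 1734, 9 of 20 for element 630 and 3 of 20 for element 911.

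Of the 42 elements that differed at 6 h and could be tested for a change from low light with limma, 0 passed the threshold adjusted over all elements and 29 had an unadjusted p under 0.05. They were chosen by the same 6 h ratio, which raises that share. Over all 2032 tested elements the number was 235. Adjusted over the locus-tagged elements alone, 3 of 78 passed for the change from low light to 6 h, 0 of 89 for that to 1 h and 3 of 75 from 1 h to 6 h. All 12 slides in 1 fit with the biological sample as a random block gave 35 changes from low light to 6 h, 28 negative. With a dye term there were 31, 26 of them negative. These fits in effect counted the exchanged slides of a biological sample as separate values. Of the 40 elements that differed at 6 h and were measured at all times, 29 had the same sign at the 3 time points.

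Some elements passed the test at more than 1 time point. Elements 1018 and 1198 passed at all 3. Their ratios in low light, at 1 h and at 6 h were -0.65, -0.54 and -0.54 for element_1018 and -1.10, -1.02 and -1.25 for element_1198; element 1018 lies outside the rule for naming and was chosen after its values were seen. In all, 58 elements passed at 1 time point or more. Low light and 1 h shared 4 elements with negative ratios, where 0.032 would be expected from independent lists, and low light and 6 h shared 3, where 0.103 would be expected. The 1 h and 6 h lists shared 2 with negative and 2 with positive ratios, against 0.177 and 0.018 expected, and 0 shared elements had opposite signs in any pair of lists. The time points have samples of their own but share the estimate of each element's spread, so the lists are not fully independent. A dye effect left in the means of exchanged slides could also recur at each time point, which was not tested. The mean ratios correlated across all elements with r = 0.42 between low light and 1 h, 0.31 between low light and 6 h and 0.45 between 1 h and 6 h.

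Differences of 2-fold in both biological samples were rare. Element 2424 met this size in low light, with log2 ratios of -1.57 and -1.04 in the 2 biological samples. At 1 h it was met by element 911 (-1.39 and -1.60) and element 888 (1.51 and 2.01), and at 6 h by element 1198 (-1.03 and -1.47). Between 0.0040 and 0.0094 elements per time point would be expected if the 2 samples were unrelated. Elements 2424 and 888 did not pass limma's test, with adjusted p = 0.0599 and 0.0595. With 1.5-fold in place of 2-fold the counts were 10 in low light, 9 at 1 h and 11 at 6 h.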

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

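The tests of a dye effect, of the signal left after averaging, of the shared spread and of single spots were chosen after the results they bear on were seen. The others were fixed before.

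Slides with exchanged channels ran opposite ways across elements, with r from -0.57 to 0.13, although their ratios are described as running the same way. Slides left unturned stay open as a cause: 100% of 20 instances of large ratios, from 13 elements, had the same sign on both exchanged slides, where large strain differences on unturned slides would have opposite signs, but a large dye bias would keep its sign there, so the test set beforehand does not separate the readings. Whether the averages carry a signal of the time point also stays open: the mean of the exchanged slides correlated better within than between time points, by 0.19 on average, but only the low light value (0.62) lay above all values between time points (0.17 to 0.49), and those at 1 h (0.38) and 6 h (0.42) did not. A dye effect of each element may account for the pattern: the difference between exchanged slides was shared between time points with a mean r of 0.64, as much as within them (0.64). A constant strain difference on unturned slides would give that correlation too, so the reading rests on the labels.

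More elements passed at 6 h (43) than in low light (8). Subtracting regional trends left a ratio of these counts of 7.17 and centring each slide one of 6.83, which argues against both as the cause of this ratio. Regional trends stay open for the wider excess at an unadjusted p under 0.05. Subtracting them lowered that number from 461 to 265 at 6 h, while in low light it was 191 before and 195 after. The biological samples did not lie closer at 6 h: the median size of their difference was 1.61 times that in low light. The shared spread may account for the excess, since with each time point's own spread the ratio of the counts was 0.56 (64 against 114). A stronger strain difference after 6 h of high light stays open and was not shown.

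Element 911 stood apart at 1 h, where its ratio differed from that in low light by -1.23 and from that at 6 h by 1.27 (later minus earlier). A single bad slide or spot is argued against, because all 14 spots with a value on the 4 slides at 1 h lay below -0.5, between -1.99 and -1.23, against 3 of 29 at the other times. A smear shared with neighbouring spots is argued against as well, because the neighbours had a median ratio of 0.0051. A transient difference between the strains at 1 h remains as a hypothesis if the slides were turned as described. Unturned slides, left open above, a mix-up of RNA and a cross-hybridising transcript were not tested for this element. The change from low light lost its call without either 1 h biological sample, although its size stayed between -1.37 and -1.07 over 21 alternatives.

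Tests of the change between time points also picked out element 293 from low light to 6 h (1.13) and, from 1 h to 6 h, element 630 (0.67), CHLRE_16g673650v5 (-0.69) and element 1734 (-0.63). Among the 4 low light slides, the slide of biological sample 2 with the mutant in channel 1 stood apart from the rest in the SD of its log2 ratios, 0.41, and in its share of spots at 0, 22.3%. Of 74 such searches for a distant slide or value these 2 were positive, and chance alone gives about 1 in 20.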

How the results depend on the processing

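The spot minimums, zeros kept as values, the running median, array weights, the omitted slides and the crossed block were chosen after the data were seen. No named ratio changed sign in any alternative run. For ratios at a time point this was largely fixed by the naming rule, which asks for the same sign on every slide. Several alternatives also leave the ratio itself as it is. Counts below are for low light, 1 h and 6 h, and then for the changes from low light to 1 h, from low light to 6 h and from 1 h to 6 h; the values of the reported test were 8, 16, 43, 1, 1 and 4, and the cause of a shift was not tested unless stated.

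Scaling gave 20 in low light (8 positive and 12 negative, against 1 and 7), 2 to 1 h and 1 between 1 h and 6 h. Centring gave 6 in low light (0 positive), 0 to 6 h and 1 between 1 h and 6 h, and the latter 1 was positive under both, against 2 and 2. The scaled change to 6 h was 1 negative element in place of 1 positive.

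All 12 slides with a random block gave 49, 74, 119, 2, 35 and 38, and with a dye term 53, 76, 101, 4, 31 and 42. The correlation between slides of a biological sample was estimated at -0.58 without and -0.07 with the dye term. The block therefore did not hold the exchanged slides as 1 replicate, and they counted as separate values. Where several elements passed for the change to 6 h most were often negative. These were 28 of 35 and 26 of 31 in the 2 fits of all slides, and 14 of 15 with at least 3 spots. They were 7 of 7 with zeros kept and 9 of 9 without the slides of poor agreement. For elements with values on all slides they were 7 of 10, and with the replicate block and with array weights 10 of 13 each. Leaving out a low light biological sample gave no clear majority of negative elements. Slides with wild type in channel 1 gave 40, 239 and 438 (34, 211 and 328 positive), and 5 to 6 h. Most calls there were positive, but all 8, 16 and 43 elements of the reported test kept their sign. Slides with the mutant in channel 1 gave 478, 376, 21, 0, 0 and 0 (415, 318 and 20 negative). This turns the order of low light and 6 h, while 8, 16 and 42 of the reported calls kept their sign. Of the 26 named calls, 14 were lost on slides with the mutant in channel 1 and 3 on slides with wild type there. Any dye effect is left in these 2 settings by construction.

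Own spread gave 114 and 81 (64 at 6 h), and 2 to 1 h and 19 between 1 h and 6 h. At 1 h limma's adjusted p for element 911 was 4.0e-42 in that fit. With 2 samples this is reached only where all elements share nearly 1 spread, so the 81 were hardly judged by their own. Array weights gave 111 in low light (29 at 6 h), 2, 13 and 1. Both turn the order of low light and 6 h. Elements with values on all slides gave 10 to 6 h, and medians of spots 0. A minimum of 3 spots gave 27, 28, 4 and 15 (low light, 1 h, and the changes from low light), and of 1 spot 0 to 6 h and 1 between 1 h and 6 h. Zeros kept gave 25 and 25, then 7 to 6 h and 2 between 1 h and 6 h. The running median gave 0 to 6 h and 1 between 1 h and 6 h. Without the 3 slides of poor agreement between copies, 1 per time point, the counts were 14, 31, 2, 9 and 21, and 51 at 6 h. This setting used the fit of single slides with a random block and a dye term. Its counts are to be set against those of that fit on all 12 slides (53, 76, 101, 4, 31 and 42), and each was lower.

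Without 1 biological sample, the counts ranged from 1 to 20 in low light, 1 to 37 at 1 h, 30 to 57 at 6 h, 0 to 3, 0 to 11 and 0 to 19; the remaining sample is assumed to vary like those of the other time points. The lows of the counts in low light and at 6 h came without either 1 h sample, and at 1 h without biological sample 2 of 1 h.

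The replicate number as a block gave 28, 26, 3, 13 and 16 (and 59 at 6 h). Deviations of samples with the same number correlated across elements with r = 0.23 between low light and 1 h, but with -0.02 between low light and 6 h and -0.15 between 1 h and 6 h, so the numbers are not read as pairs over the 3 time points. A crossed block gave 43 between 1 h and 6 h.

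The 2-fold rule at 1.5-fold gave 10, 9 and 11, and on all 4 slides 0 in low light and 0 at 6 h. The list test and its alternatives were not run. Among the limits of the slides were unmeasured spots, up to 43.4%, and the agreement of copies. The limits were not ranked, and signal over background is not given.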

Other observations

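Locus-tagged elements were over-represented among those that differed at 6 h, a comparison made after the results were seen. Of 79 tested, 8 passed (10.1%), all with negative ratios, against 35 of 2060 other elements (1.70%; 28 negative; Fisher's exact test, two-sided, p = 1.23e-04). In low light 1 of 94 passed (p = 0.274) and at 1 h 0 of 93 (p = 1, Fisher's exact test). Among all tested locus-tagged elements at 6 h, 36 had positive and 43 negative ratios, with a median of -0.01 against 0.03 for the others, and no test of a group shift was run. The share was 26.6% against 20.2% on slides with wild type in channel 1 (p = 0.1997, Fisher's exact test) and 3 of 102 against 30 of 2543 without biological sample 2 of 6 h (p = 0.132, Fisher's exact test). With each time point's own spread 9 of 79 passed against 55 of 2060 (p = 4.26e-04, Fisher's exact test).

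The size of the log2 ratios that both biological samples shared was estimated at the 3 time points. A dye effect left in the means or a regional trend common to both samples would enter this size as well. It was not shown to be the strain difference alone. Taken as the square root of the covariance between the 2 samples over 1895 elements measured throughout, it was 0.115 in low light (95% interval from resampled elements 0.1002 to 0.130), 0.112 at 1 h (0.0921 to 0.133) and 0.132 at 6 h (0.119 to 0.146) on the log2 scale. The intervals overlap, and elements are not independent. Spearman's rho between the 2 samples over these elements was 0.471, 0.158 and 0.372, against Pearson's r of 0.629, 0.410 and 0.434, so the ranks matched least at 1 h, and the sizes are not shown to be alike. This comparison was made after the counts were seen.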
